A study of Rattus norvegicus with 19 samples.

How the data were processed

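Nuclei were isolated on an iodixanol gradient from punches of snap-frozen amygdala cryosections of 19 male outbred rats and profiled with a droplet-based 3' kit, per the labels. The deposited matrices held, for each library, the UMI count of each gene in each barcode, and were used as they were. The submitters' processing notes name Cell Ranger and Seurat and the rat genome build Rnor_6.0, and the matrix headers give software version 3.1.0 for all 19 libraries. The annotation release was not given in the sources used here. The deposited metrics list 0% of reads as intronic and 61.5% to 64.5% as exonic. Reads, genotypes and behavioural scores were not analysed here. Replicates were numbered in the order of their records, and no paired analysis was possible because the labels pair no animals.

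Barcodes with at least 500 genes and at most 5% mitochondrial UMIs passed, which left 158955 nuclei, and Scrublet in scanpy 1.11.5 called 6603 of them doublets (4.15%), so that 152352 were kept over 25399 genes. Counts were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1, without batch integration, gave 28 clusters. A cluster took the name of a class when at least 3 of its markers were detected in 10% of nuclei at 1.5 times the level elsewhere, no second class scored above 0.75 of the first, and at most 40% of its barcodes were doublets. It stayed unnamed when its leading genes held more markers of another class than of its own, or when it had few UMIs and no marker among them. The markers were fixed before the data were examined, while these naming thresholds were set after the clusters were seen. Inhibitory nuclei were clustered again at resolution 0.5. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

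UMI counts were summed per library and class, in classes with at least 20 nuclei in a library and at least 4 such libraries per group. The smallest sums came from committed precursors, with 22 to 89 nuclei per library, and from microglia, with 81 to 675, and few counts limit precision there. Genes were kept by filterByExpr and tested two-sided with edgeR 4.0.16 in R 4.3.3 (TMM scaling, robust quasi-likelihood fit of the 3 groups), with Benjamini-Hochberg adjustment over all genes of a class and a threshold of 0.05. DESeq2 1.42.0 was run on the same counts. The fitted log2 differences are given with their SE, and CPM as means over libraries with SD. The difference between the effects in inhibitory and excitatory neurons was tested with limma 3.58.1. The 25 gene lists were tested by camera with a preset correlation of 0.01, adjusted over all 163 list-class pairs of a comparison with at least 5 measured genes, and again by camera with the correlation estimated per list and by fry. Shares of nuclei were compared by two-sided permutation tests on the difference of means, exact in all 4 comparisons, with Benjamini-Hochberg adjustment over the 7 classes or the 16 inhibitory subclusters. For shares of nuclei with UMIs of activity genes, each nucleus was thinned at random to 1500 UMIs, and nuclei with fewer were left out.

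The comparisons, classes, lists, tests, named-gene rule and most alternatives were chosen before the data were examined. The rule named every call, the 20 list members with the smallest p in each of the first 2 comparisons, a few genes such as Glo1, Gabrb2, Crh and Fkbp5 in both neuron classes, and up to 4 members of each called list. Some genes that the rule covers are not reported here. Of the last, the text names only leading members, a narrowing made after the list results were seen, which also limits the search for outlying libraries to 72 gene-class pairs. P22k15, Arhgef26, Vegfa and Fam163a lie outside the rule and were named after their values were seen. The alternatives were DESeq2 size factors, no gene filter, DESeq2, only the groups compared, at least 1000 genes per nucleus, doublets kept, at least 50 nuclei, covariates for the tag number series (5 libraries in the 120 series and 14 in the 320 series) and for median UMIs, Leiden resolution 0.4, subclustering at 0.25, other measures of a share, and each library left out. The 120 series held low 1, low 2, low 6, high 6 and naive 1, so it was partly confounded with high against low. Chosen after seeing the data were a fit without the 3 deeply sequenced libraries, covariates for deep sequencing and for the median mitochondrial percent, and a maximum of 1% mitochondrial UMIs. Scaling by DESeq2 size factors moved the median over all genes by at most -0.0071 on the log2 scale.

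Libraries were checked for duplicates in 51 pairs within groups, where the chi-square per degree of freedom ran from 9.71 to 209, against 1 for counting noise alone. The tests were tried on simulated data with the depth and spread of the real libraries. In each class tested in this way 200 genes were changed, over all fold sizes. Recovery with fewer changed genes, where the adjustment is stricter, was not simulated. Between high and low animals edgeR recovered 35.4%, 78.6%, 95.4% and 95.4% of genes changed 1.5-fold, 2-fold, 3-fold and 4-fold, and between cocaine and naive animals 54.3%, 86.6%, 93.7% and 93.1%. The limma test of the difference recovered 18%, 64%, 82% and 86%. A planted list of 15 genes changed 1.25-fold was called in 6 and 7 of 7 classes, with 2 of 161 and 1 of 162 other list-class pairs called. Genes were drawn independently there, so a correlation between the genes of a list was not part of that check. Each comparison with groups of libraries was also repeated over 100 splits of the same libraries.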

Results

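Nuclei from amygdala punches of 19 male outbred rats were profiled by droplet-based single-nucleus RNA sequencing, with 1 library per animal. Of these animals, 12 had self-administered cocaine for 2 h per day over 10 days and then for 6 h per day over 14 days. Their tissue was taken after 4 weeks of abstinence. Behavioural measures of drug taking had placed 6 of them in a group with a high addiction index and 6 in a group with a low index. The other 7 rats were naive to the drug. The 2 cocaine groups were compared with each other, jointly with the naive rats, and each with the naive rats. Libraries held between 17407556 UMIs (naive 5) and 49315646 UMIs (high 2) in the barcodes deposited, and 5154 (naive 7) to 12083 (high 2) nuclei were kept per library. Sequencing reached 11967 to 19201 reads per nucleus in 16 libraries, and 50343, 40217 and 36467 in high 6, low 6 and naive 7, so that each group held 1 library sequenced more deeply than the rest. The median mitochondrial share of UMIs per library was 0.460% ± 0.234 (SD, n = 12) in cocaine and 0.658% ± 0.214 (SD, n = 7) in naive animals (two-sided exact permutation test, p = 0.0839).

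Clustering of 152352 nuclei gave 28 clusters, of which 21 were named from markers fixed beforehand. Inhibitory-neuron-like nuclei, which held Gad1 at 507 CPM and Gad2 at 608 CPM, were the most frequent class with 55050 nuclei (36.1%). Excitatory-neuron-like nuclei, with Slc17a7 at 463 CPM, numbered 23601 (15.5%). Among glia, 24721 nuclei (16.2%) were oligodendrocyte-like with Mog at 2441 CPM and 17856 (11.7%) astrocyte-like with Gja1 at 1389 CPM. There were 8947 (5.87%) oligodendrocyte-precursor-like nuclei with Pdgfra at 1553 CPM, and 7300 (4.79%) microglia-like ones with Csf1r at 1369 CPM. A further 1015 nuclei (0.666%) were like committed oligodendrocyte precursors, with Enpp6 at 855 CPM and Bmp4 at 712 CPM. Of that cluster 14.1% had been called doublets and removed. The shorter class names used from here on stand for these marker-defined groups. Free RNA was visible in every class, since Gad2 reached 210 CPM in microglia and 142 CPM in oligodendrocytes. Within inhibitory neurons, 16 subclusters were found, of which 8 could be named. Of these, 2 were like D1 and 1 like D2 projection neurons, 2 like Pvalb interneurons, and 1 each like Sst, Vip and Lamp5 interneurons. A score, the mean log2 ratio of a class's markers to the other nuclei clustered, had no minimum. It was 0.0755 for the larger D1-like subcluster (3 of 7 markers), and 0.547 and 0.923 for the Pvalb-like ones. A subcluster with a Pvalb score of 1.84 stayed unnamed. Neuron clusters led by Drd2 (-0.437), Scn4b (-0.197), Lhx8 (-0.0313) and Pappa2 (-0.198) were named with a score below 0. A cluster of 1650 inhibitory nuclei was led by the immediate early genes Fosb and Fos. It made up 1.28% ± 0.362 (SD, n = 12) of nuclei in cocaine and 0.790% ± 0.237 (SD, n = 7) in naive animals (two-sided exact permutation p = 0.00460, adjusted p = 0.129 over all 28 clusters). Its share was 1.24% ± 0.170 (SD, n = 6) in high and 1.31% ± 0.506 (SD, n = 6) in low animals (exact permutation p = 0.738), with adjusted p = 0.114 for high and 0.432 for low against naive animals. This cluster was singled out for its markers after the clusters were seen. The 7 unnamed clusters held 13862 nuclei, which was 9.5% ± 1.02 (SD, n = 6) of nuclei in high, 9.20% ± 1.36 (SD, n = 6) in low and 8.65% ± 1.24 (SD, n = 7) in naive libraries. The neuronal gene Snap25 stood at 1079 CPM in them, against 1563 CPM in excitatory and 1214 CPM in inhibitory neurons. Among glia it reached at most 618 CPM, in microglia. An unnamed cluster of 5552 nuclei was led by Slc17a6. Many unnamed nuclei were thus neuron-like, and the shares and tests of both neuron classes leave them out.

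**Figure D1:**
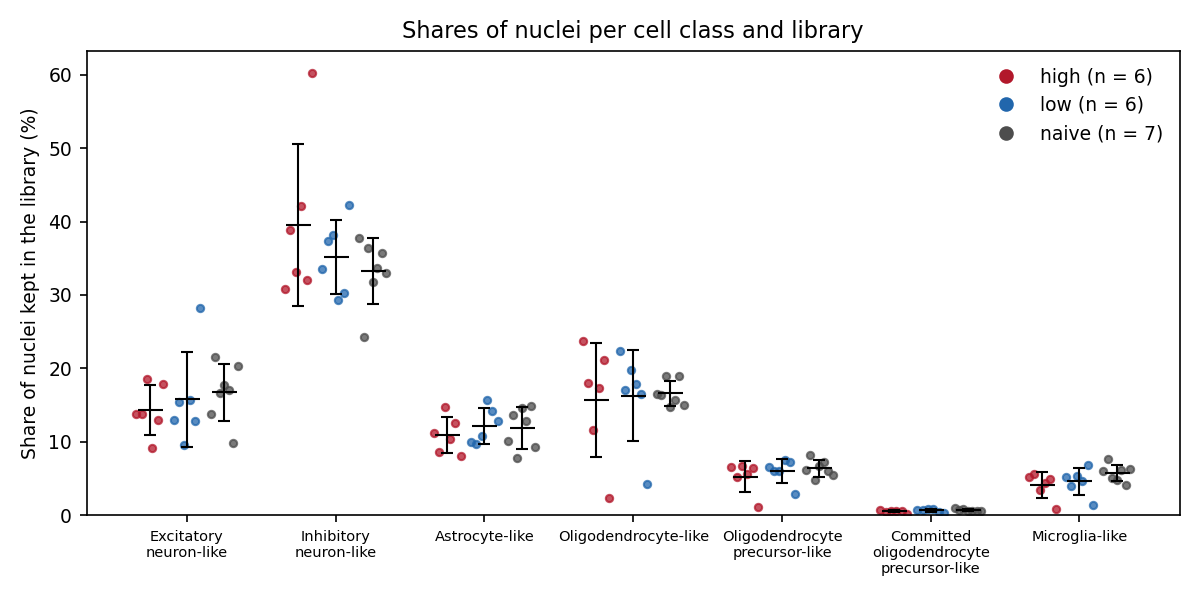
Share of nuclei (percent) in each of the 7 classes, with 1 point per library and the group mean ± SD for high (n = 6), low (n = 6) and naive (n = 7). Oligodendrocytes made up 2.34% of nuclei in high 6 and 4.32% in low 6, against at least 11.6% in each of the other libraries.

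The comparison of high with low animals asked which genes differ within a cell class between rats that took the same drug under the same schedule and differ in addiction index. In oligodendrocyte precursors, Sparcl1 (ENSRNOG00000015093), which encodes a secreted protein of the SPARC family, stood at 247 CPM ± 37.2 (SD, n = 6) in high and 131 CPM ± 19.7 (SD, n = 6) in low animals. The log2 difference was 0.89 ± 0.15 (SE). Sparcl1 was higher in 6 of 6 high libraries than in any low library. Naive libraries held 218 CPM ± 61.0 (SD, n = 7), nearer to the high than to the low mean. In microglia, Pex5l (ENSRNOG00000011211), whose protein TRIP8b is an auxiliary subunit of HCN channels, rose to 70.1 CPM ± 31.8 (SD, n = 6) from 30.2 CPM ± 13.4 (SD, n = 6). The log2 difference was 1.41 ± 0.27 (SE), with naive libraries at 50.5 CPM ± 12.3 (SD, n = 7). Only 161 and 57 UMIs lay behind the high and low values of Pex5l, and 4 of 6 high libraries exceeded every low library. Oligodendrocytes of the high libraries held 1879 CPM ± 444 (SD, n = 6) of the same transcript. Excitatory neurons of these libraries held 883 CPM ± 246 of it and inhibitory neurons 390 CPM ± 69.3. For Pex5l a change in free RNA was not told apart from a change within microglia. Sparcl1 and Pex5l were the 2 calls of edgeR among 68848 gene-class pairs, with adjusted p = 0.0146 for Sparcl1 and adjusted p = 0.0379 for Pex5l. At an unadjusted p under 0.05 there were 1163 pairs (1.69%), a smaller share than this threshold gives with no difference at all. DESeq2 called 1 pair, Sparcl1 (adjusted p = 0.000973, against 0.0834 for Pex5l). Sparcl1 lost its call without high 1 (adjusted p = 0.0620), low 1 (0.0745), low 2 (0.0817), low 4 (0.0839) or high 4 (0.120). It also did so with the tag number series as a covariate (0.0935) and without the 3 deeply sequenced libraries (0.156), while its log2 difference stayed at 0.79 or more in every setting. Pex5l lost its call without naive 3 (0.0529), naive 1 (0.0569), naive 5 (0.0576) or naive 4 (0.0602). It did so too without low 2 (0.0810), high 4 (0.0810), low 5 (0.0845), low 1 (0.239), low 4 (0.243), high 3 (0.278), low 3 (0.448) or high 2 (0.880). Its adjusted p was 0.0970 with the tag number series, 0.135 with only the groups compared, 0.478 with at most 1% mitochondrial UMIs and 1.0 with doublets kept, where its log2 difference fell to 0.465. The count of calls was 3 without low 6, with Fam163a in oligodendrocytes added.

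**Figure D2:**
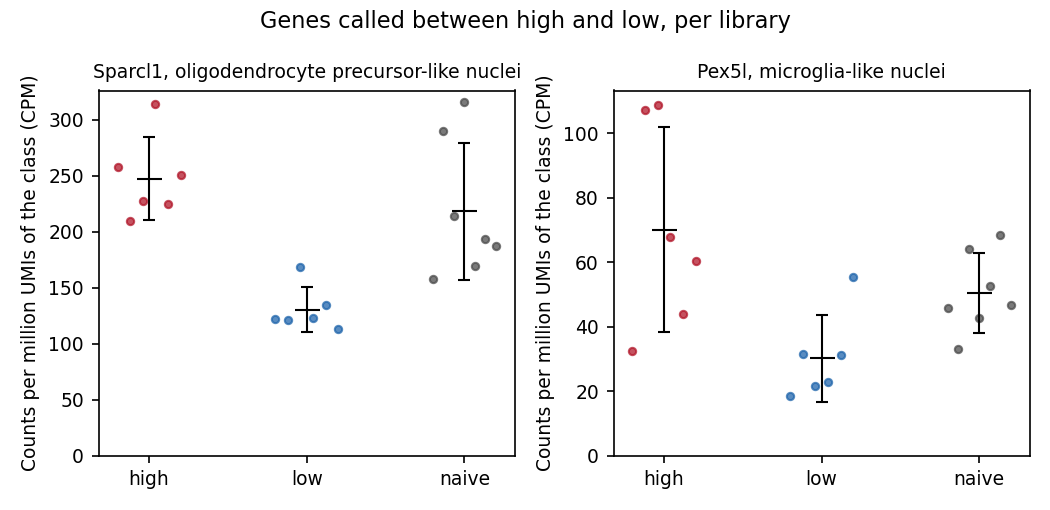
Expression (CPM) of Sparcl1 in oligodendrocyte precursors and of Pex5l in microglia, with 1 point per library and the group mean ± SD for high (n = 6), low (n = 6) and naive (n = 7). All 6 high libraries lay above all 6 low libraries for Sparcl1, and 4 of 6 did for Pex5l.

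Of the gene lists fixed beforehand, myelin and oligodendrocyte maturation genes had the smallest p, in microglia. Every rise or fall of a list given for this comparison was called by camera at its preset correlation only, and all 15 had adjusted p = 0.997 with an estimated correlation. In microglia all 11 measured members were higher in high than in low animals with a median log2 difference of 0.58. Mbp, a main protein of compact myelin, stood at 0.58 ± 0.17 (SE, n = 6 and 6), Mobp at 0.80 ± 0.27 and Mog, a surface protein of myelin, at 1.0 ± 0.40. With doublets kept these fell to 0.33, 0.44 and 0.28, and Mog stood at 0.64 without high 2. Other transcripts from outside the list, which oligodendrocytes hold at 10 or more times the level of neurons, astrocytes and oligodendrocyte precursors, had a median log2 difference of 0.36 in the same microglia, with 15 of 16 above 0 and 4 at an unadjusted p under 0.05, and were not tested as a list. Levels in microglia played no part in that choice. Rasgrp3 (log2 difference 0.0097) and Enpp6 (-0.086) stood at 314 and 116 CPM in microglia, above their 180 and 84.7 CPM in oligodendrocytes. Mitochondrially encoded genes fell in excitatory neurons (median -0.25, 12 of 13 members negative) and in inhibitory neurons (-0.14, 11 of 13). Immediate early genes, which neurons induce on activity, fell in inhibitory neurons (median -0.21, 19 of 21 negative), excitatory neurons (-0.20, 17 of 21) and astrocytes (-0.25, 13 of 16). Among them Fos and Junb stood at -0.47 ± 0.31 and -0.28 ± 0.19 in inhibitory neurons, and Fos at -0.30 without low 4. Genes of cholesterol biosynthesis fell in astrocytes (-0.17, 17 of 19) and in excitatory neurons (-0.09, 15 of 20). Glucocorticoid-responsive genes rose in oligodendrocytes (0.40, 12 of 13) and microglia (0.30, 7 of 9). Smaller rises were called for dopamine signalling and striatal projection neuron genes in inhibitory neurons (0.15, 13 of 13) and for cytosolic ribosomal protein genes in astrocytes (0.08, 52 of 61). Nuclear-encoded oxidative phosphorylation genes rose in astrocytes (0.07, 62 of 74), oligodendrocyte precursors (0.04, 49 of 73) and committed precursors (0.12, 43 of 59). These last 5 did not hold their direction in camera. The dopamine and striatal list turned down without the 3 deeply sequenced libraries (adjusted p = 0.588) and without low 6 (0.926). The ribosomal list (0.412) and the oxidative phosphorylation lists (0.278 in astrocytes, 0.241 in oligodendrocyte precursors and 0.811 in committed precursors) turned down without high 6. Camera with its preset correlation called these 15 of 163 list-class pairs, 8 up and 7 down, from adjusted p = 3.28e-08 for myelin genes in microglia to adjusted p = 0.0458. Camera called 0 when the correlation was estimated (adjusted p = 0.997 with an estimated correlation, with 3 of the 163 pairs at an unadjusted p under 0.05), and fry called 0 (smallest adjusted p = 0.992). Adjusted over the list alone, 4 list members were called, against 0 list members over all genes tested by edgeR.

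Calls of 2 of the 15 lists, myelin genes in microglia (highest adjusted p = 1.43e-05) and cholesterol genes in astrocytes (0.0467), lasted whichever library was left out, at the preset correlation. Both ended in camera when it was estimated (adjusted p = 0.997 with an estimated correlation). The calls of mitochondrially encoded genes ended without low 2, high 4 or high 6, at adjusted p up to 0.273 in excitatory and 0.675 in inhibitory neurons. Those of immediate early genes ended without low 4 in inhibitory neurons (0.0922) and without low 4, low 5, high 5 or high 6 in excitatory neurons (up to 0.391). In astrocytes they ended without high 4, low 3, low 4 or high 5 (up to 0.391). Cholesterol genes in excitatory neurons lost theirs without high 3 or high 4 (up to 0.247), and glucocorticoid-responsive genes in oligodendrocytes without low 4 (0.123). In microglia the latter did so without high 1, low 1, low 2, high 4, low 4, naive 6, low 5, high 5 or high 6 (up to 0.188). Oxidative phosphorylation genes lost theirs without high 1, low 2, low 5 or high 6 in astrocytes (up to 0.735), and without these or low 3 or low 4 in oligodendrocyte precursors (up to 0.976). In committed precursors they did so without any of these 6, naive 4, naive 6 or naive 7 (up to 0.811). Ribosomal protein genes in astrocytes did so without high 1, low 2, low 3, low 5 or high 6 (up to 0.733), and the dopamine and striatal list without high 2, high 4, low 5, high 6 or low 6 (up to 0.926). The number of called lists was 9 without low 4, 25 without high 3, 26 without high 6 and 30 without low 6.

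Other settings ended calls of these lists as well. At the preset correlation 5 of the 15 kept their call in every setting that left out no single library, and all 5 lost it in camera otherwise (adjusted p = 0.997 with an estimated correlation). They were mitochondrially encoded genes in excitatory neurons, cholesterol genes in excitatory neurons and astrocytes, immediate early genes in inhibitory neurons and myelin genes in microglia. Without the 3 deeply sequenced libraries 6 of the 15 calls ended: mitochondrially encoded genes in inhibitory neurons, immediate early genes in excitatory neurons, the dopamine and striatal list, ribosomal genes in astrocytes, and oxidative phosphorylation genes in astrocytes and oligodendrocyte precursors. With no gene filter 8 ended, namely glucocorticoid-responsive genes in oligodendrocytes and microglia, immediate early genes in astrocytes, the dopamine and striatal list, ribosomal genes, and oxidative phosphorylation genes in all 3 classes. With at least 1000 genes per nucleus 5 of 13 tested ended: glucocorticoid-responsive genes in oligodendrocytes, ribosomal genes, and oxidative phosphorylation genes in all 3 classes. With the median mitochondrial percent as a covariate 4 ended, those of ribosomal genes, of oxidative phosphorylation genes in both precursor classes, and of glucocorticoid-responsive genes in microglia. The last also ended with at most 1% mitochondrial UMIs, and oxidative phosphorylation genes in committed precursors with doublets kept or at Leiden resolution 0.4.

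Members of the fixed lists with the smallest p, none past the threshold, included further genes of each class. In microglia these were Kcnq3, a potassium channel gene, at 1.02 ± 0.37 (SE) on the log2 scale and the kinase gene Sgk1, a target of glucocorticoids, at 0.61 ± 0.23. The same class gave Atp5mf at 0.43 ± 0.18 and the chaperonin gene Hspe1 at -0.80 ± 0.33. Committed precursors gave Gad2, which makes GABA, at 1.07 ± 0.30 and the sodium channel gene Scn1a at 0.67 ± 0.27. They also gave Aldh5a1, which acts on a product of GABA in its breakdown, at -0.81 ± 0.30. Gad2 there stood at 88.1 CPM over all libraries, below oligodendrocyte precursors (124 CPM), oligodendrocytes (142 CPM) and microglia (210 CPM). At that level a change in free RNA cannot be told apart from a change within the class. For the other genes of channels, receptors and synapses named in glial classes here, it was not told apart either. Astrocytes gave the opioid receptor gene Oprm1 at 0.66 ± 0.26, Dlgap3 at 0.58 ± 0.20, Unc13b at -0.60 ± 0.22, Egr4 at -0.49 ± 0.19 and Fdft1, an enzyme of sterol synthesis, at -0.32 ± 0.12. In oligodendrocyte precursors Gpnmb stood at -0.52 ± 0.19. In oligodendrocytes Rpl32 stood at 0.67 ± 0.27, in excitatory neurons Zbtb16 at 0.48 ± 0.15, and in inhibitory neurons Hk2 at 0.75 ± 0.30, with 1.04 CPM in high animals. Several of these shrank by more than 1.5 times in other settings. Leaving out 1 library took Kcnq3 to 0.65 (without high 2), Hspe1 to -0.50 (without low 3) and Gpnmb to -0.31 (without low 6). With doublets kept Kcnq3 fell to 0.0155, Gad2 to 0.26, Oprm1 to 0.31 and Unc13b to -0.30. The naming rule gave 35 gene-class pairs for this comparison, among them Mt-nd4l and Mt-nd6 in both neuron classes, whose values are not given here. Of the 35, 16 shrank by so much or turned when 1 library was left out, these 4 included, and 17 in another setting. In edgeR each of these 16 list members, and Mbp, Mobp and Mog, had an adjusted p of at least 0.999.

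Genes of GABA-A receptors and of stress that were chosen in advance showed small differences in neurons, each with an edgeR adjusted p above 0.999. Glo1, whose enzyme clears methylglyoxal, a GABA-A receptor agonist, stood at 0.01 ± 0.20 (SE) in excitatory and 0.02 ± 0.18 in inhibitory neurons. The receptor subunit gene Gabrb2 stood at -0.07 ± 0.14 in excitatory and 0.04 ± 0.11 in inhibitory neurons. Crh, the gene of the stress peptide corticotropin-releasing hormone, stood at 0.03 ± 0.40 and -0.03 ± 0.24, and Fkbp5, a chaperone of the glucocorticoid receptor, at 0.32 ± 0.17 and 0.09 ± 0.14. Over all libraries Crh stood at 24.65 CPM in the unnamed nuclei, against 14.3 CPM in inhibitory and 3.68 CPM in excitatory neurons. The unnamed nuclei, among them a cluster of 1486 with Crh among its leading genes, were not tested. Crh in excitatory neurons was measured at only 4.15 CPM in high animals and turned to -0.49 without high 6. Leaving out 1 library also turned the sign of Glo1, to as low as -0.19 in excitatory and -0.17 in inhibitory neurons without high 6, of Gabrb2 in inhibitory neurons (to -0.01 without low 6) and of Crh in inhibitory neurons (to 0.16 without low 4). Without low 4, Fkbp5 in inhibitory neurons also shrank to 0.0257 and Gabrb2 in excitatory neurons to -0.0044. In simulated counts with the same library sizes, pooled over 7 classes, edgeR recovered 35.4% of genes changed 1.5-fold and 78.6% of those changed 2-fold. Over all classes, most changes under 1.5-fold would thus have been missed in this comparison. The simulation changed 200 genes in each class. With fewer changed genes the adjustment is stricter, so recovery can be lower, which was not simulated. Recovery in the neuron classes alone is not given here. The difference between the high-low effects of the 2 neuron classes was tested directly with limma for 13292 genes, of which 0 passed (smallest adjusted p = 0.660; 453 at an unadjusted p under 0.05).

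No class differed in its share of nuclei between high and low animals in two-sided exact permutation tests over 7 classes. Inhibitory neurons made up 39.5% ± 11 (SD, n = 6) of nuclei in high and 35.1% ± 5.02 (SD, n = 6) in low animals (exact p = 0.461, adjusted p = 0.843). High 6 held 60.2% inhibitory nuclei against 30.8% to 42.1% in the other high libraries, and without it the high mean was 35.4%, so that the difference of 4.40 points fell to 0.259. Excitatory neurons made up 14.4% ± 3.44 against 15.8% ± 6.49 (exact p = 0.723, adjusted p = 0.843), and oligodendrocytes 15.7% ± 7.72 against 16.3% ± 6.25 (exact p = 0.872). Both differences turned with 1 library left out, to 1.05 points for excitatory neurons without low 6 and to 2.08 for oligodendrocytes without high 6. Among the 16 inhibitory subclusters, the D2-projection-like one held 10.9% ± 3.68 of inhibitory nuclei in high and 8.82% ± 4.87 in low animals (exact p = 0.429, adjusted p = 0.713). That difference of 2.08 points became 0.554 without low 6, and 0 subclusters passed, with a smallest adjusted p of 0.681.

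Cocaine and naive animals were compared to find what a history of cocaine self-administration leaves in each class after abstinence. The labels give no access sessions for naive animals, so the drug and the self-administration procedure cannot be told apart here. The 2 lists given first were called by camera at its preset correlation only (adjusted p = 0.493 with an estimated correlation in every class called). Mitochondrially encoded genes, which code for subunits of the respiratory chain, fell in 6 of 7 classes. Their median was -0.53 in excitatory neurons and -0.52 in inhibitory neurons (13 of 13 members negative in both). In glia it was -0.39 in astrocytes (12 of 12), -0.37 in committed precursors (8 of 8), -0.36 in oligodendrocyte precursors (12 of 12) and -0.35 in oligodendrocytes (11 of 12). Mt-nd3 stood at -0.59 ± 0.26 (SE, n = 12 and 7) in excitatory and -0.63 ± 0.26 in inhibitory neurons, and Mt-cyb at -0.42 ± 0.16 in astrocytes, -0.47 ± 0.24 in oligodendrocyte precursors and -0.37 ± 0.21 in oligodendrocytes. Each of these was smaller by more than 1.5 times in a setting that itself acts on the UMIs of these genes, where a smaller difference is in part built in. With at most 1% mitochondrial UMIs Mt-nd3 stood at -0.28 in excitatory and -0.29 in inhibitory neurons. With the median mitochondrial percent as a covariate Mt-cyb stood at -0.146 in astrocytes, -0.112 in oligodendrocyte precursors and -0.0406 in oligodendrocytes. Immediate early genes rose in excitatory (median 0.27, 21 of 21) and inhibitory neurons (0.27, 18 of 21). The activity-dependent transcription factor gene Npas4 stood at 0.90 ± 0.27 and 1.39 ± 0.34 in these classes and Fosb at 0.78 ± 0.28 and 0.75 ± 0.27. Camera gave adjusted p = 2.05e-17 for mitochondrially encoded genes in inhibitory neurons and adjusted p = 3.17e-10 for immediate early genes in excitatory neurons, but both lists had adjusted p = 0.493 with an estimated correlation in every class called. At the preset correlation only, all 8 calls lasted whichever library was left out. Calls of mitochondrially encoded genes in oligodendrocytes and both precursor classes ended with the library's median mitochondrial share as a covariate, that in oligodendrocytes with at least 1000 genes per nucleus, and that in committed precursors with at most 1% mitochondrial UMIs. The covariate is computed from the UMIs of the same genes, so the calls that ended with it decide neither for nor against the difference.

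Camera at its preset correlation called several further lists between cocaine and naive animals, none of which had an adjusted p below 0.493 with an estimated correlation. Cholesterol biosynthesis genes fell in astrocytes (median -0.19, 18 of 19), where the squalene epoxidase gene Sqle stood at -0.27 ± 0.10 (SE). They also fell in excitatory neurons (-0.07, 16 of 20) and oligodendrocytes (-0.08, 17 of 19). Glucocorticoid-responsive genes fell in oligodendrocytes (-0.45, 13 of 13), with Errfi1 at -0.74 ± 0.18 and Arrdc2 at -0.45 ± 0.18, and in oligodendrocyte precursors (-0.22, 7 of 9). Heat shock and chaperone genes rose in oligodendrocyte precursors (0.20, 14 of 16), oligodendrocytes (0.16, 14 of 16), astrocytes (0.10, 14 of 17) and microglia (0.09, 14 of 15). In neurons they rose in the excitatory (0.12, 15 of 16) and inhibitory class (0.10, 13 of 16), with Hsp90b1 and Cryab at 0.40 ± 0.13 and 0.44 ± 0.19 in oligodendrocyte precursors. Circadian clock genes fell in astrocytes (-0.15, 13 of 15), with Bhlhe41 at -0.60 ± 0.27 and Nr1d2 at -0.18 ± 0.09, and in excitatory neurons (-0.08, 13 of 16). In committed precursors, 5 lists of neuronal genes rose, namely sodium and calcium channels (0.32, 12 of 12) and metabotropic glutamate receptors and postsynaptic scaffold (0.26, 10 of 11). The others were potassium channels (0.17, 9 of 10), ionotropic glutamate receptors (0.15, 12 of 14) and synaptic vesicle release (0.14, 17 of 18), as did synaptic adhesion genes (0.09, 16 of 25). Microglial activation genes rose in microglia (0.11, 13 of 16) and fell in astrocytes (-0.18, 7 of 12), inhibitory neurons (-0.16, 9 of 14) and oligodendrocytes (-0.11, 8 of 10). Myelin genes fell in astrocytes (-0.13, 13 of 16) and inhibitory neurons (-0.06, 14 of 19). Astrocytic transport genes fell in inhibitory neurons (-0.14, 11 of 13). Glial markers had a UMI in few inhibitory nuclei, at 2.66% for Mog, 1.97% for Aqp4 and 0.912% for Csf1r. Falls of lists in classes that hardly hold them, and rises of neuronal lists in committed precursors, were not told apart from changes in free RNA. Oxidative phosphorylation genes rose in excitatory neurons (0.10, 72 of 75). That last direction did not hold, since without the 3 deeply sequenced libraries camera called the same list in the opposite direction, down (adjusted p = 0.0295). It also turned down without high 6 (0.550) or low 6 (0.698), with the tag number series (0.909) and with the median mitochondrial percent as a covariate (0.453). Myelin genes in inhibitory neurons turned as well, without the deep libraries (0.894) and with the median mitochondrial percent (0.311). In all, camera called 35 of 163 list-class pairs, 16 up and 19 down. It called 0 when the correlation was estimated (smallest adjusted p = 0.493 with an estimated correlation, 11 at an unadjusted p under 0.05), and fry called 0 (smallest adjusted p = 0.938). Adjusted over the list alone, 9 list members were called, against 0 over all genes tested.

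**Figure D3:**
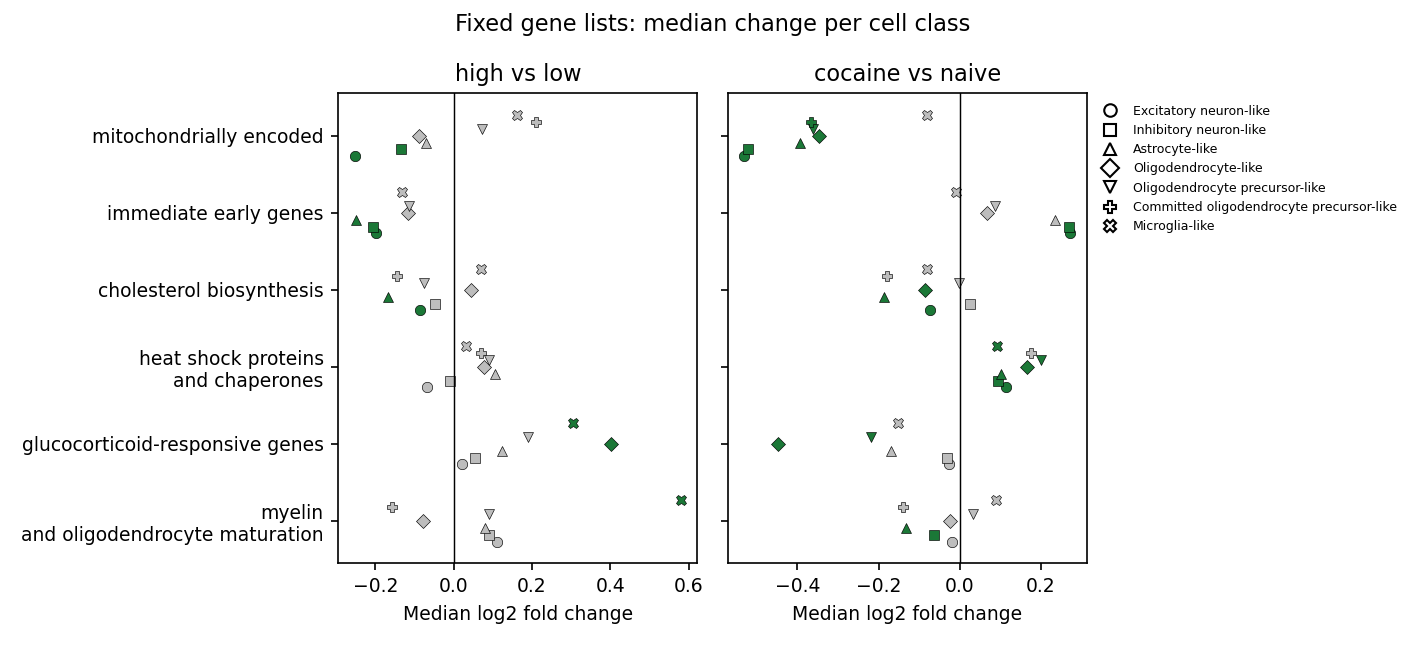
Median log2 difference of the members of 6 gene lists in each class, for high against low and cocaine against naive animals, with filled green symbols where camera called the list at its preset correlation and grey ones where it did not. The fall of mitochondrially encoded genes in cocaine animals reached -0.53 in excitatory neurons.

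Besides the 8 calls above, 6 of the 35 lasted whichever library was left out, at the preset correlation. All 35 ended in camera when it was estimated (smallest adjusted p = 0.493 with an estimated correlation). The 6 were cholesterol genes in astrocytes (highest adjusted p = 0.000104) and excitatory neurons (0.0316) and glucocorticoid-responsive genes in oligodendrocytes (0.00869). The rest were heat shock genes in oligodendrocyte precursors (0.000926), clock genes in astrocytes (0.0295), and sodium and calcium channel genes in committed precursors (0.00214). Heat shock calls ended without high 1 in excitatory (0.134) and inhibitory neurons (0.122), without high 1 or naive 2 in astrocytes (up to 0.124), and without naive 2 in oligodendrocytes (0.0703). In microglia they ended without high 1, naive 2, high 3, low 3, low 4, naive 4, high 6 or naive 7 (up to 0.247). Clock genes in excitatory neurons lost theirs without naive 3, naive 6 or high 6 (up to 0.0953), and glucocorticoid-responsive genes in oligodendrocyte precursors without naive 3, high 2, low 4 or naive 7 (up to 0.281). In committed precursors, vesicle release (up to 0.155) and adhesion genes (up to 0.230) lost theirs without naive 4 or naive 7, and metabotropic receptor genes without high 3, naive 4 or naive 7 (up to 0.268). Ionotropic receptor genes did so without naive 1, naive 3, low 3, low 4, naive 6, high 5 or naive 7 (up to 0.168). Potassium channel genes did so without naive 3, low 2, high 2, high 3, low 4, naive 4, naive 5, low 5 or naive 7 (up to 0.373). Microglial activation genes lost theirs in microglia without high 1, low 1, naive 2, naive 5, naive 6 or high 6 (up to 0.201). In inhibitory neurons this took the omission of naive 2, low 2, high 4, low 4, naive 5, naive 6, high 6 or naive 7 (up to 0.133), and in oligodendrocytes that of naive 1, naive 2, naive 3, high 4, low 4, high 5 or high 6 (up to 0.235). In astrocytes it was that of naive 1, naive 2, naive 3, high 3, high 4, low 3, low 4, high 5, high 6 or naive 7 (up to 0.372). Myelin genes did so in inhibitory neurons without naive 2, high 4, naive 6, high 6 or low 6 (up to 0.550). In astrocytes they did so without naive 1, naive 2, naive 3, high 4, naive 6, low 5, high 6 or low 6 (up to 0.276). Astrocytic transport genes in inhibitory neurons did so without naive 2 (0.115), and oxidative phosphorylation genes in excitatory neurons without high 1, naive 1, naive 3, naive 4, high 6 or low 6 (up to 0.698). Cholesterol genes in oligodendrocytes did so without naive 3, low 2, high 2, high 3, high 4, low 3, low 4, naive 4, naive 5, naive 6, high 5 or naive 7 (up to 0.222).

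In settings that left out no single library, 10 of the 35 kept their call throughout at the preset correlation, and none did otherwise (smallest adjusted p = 0.493 with an estimated correlation). They were mitochondrially encoded genes in both neuron classes and astrocytes, immediate early genes in both neuron classes, cholesterol genes in excitatory neurons and astrocytes, clock genes in astrocytes, glucocorticoid-responsive genes in oligodendrocytes and heat shock genes in oligodendrocyte precursors. In committed precursors sodium and calcium channel genes lost their call at Leiden resolution 0.4. Metabotropic receptor, vesicle release and adhesion genes did so there and with doublets kept, ionotropic receptor genes in both of these, and potassium channel genes with doublets kept. In all, 11 calls of 34 tested ended at resolution 0.4, 6 of 35 with doublets kept, 10 with no gene filter, 7 with median UMIs as a covariate and 7 of 33 tested with at least 1000 genes per nucleus. With the tag number series 4 ended, with only the groups compared 3, with at most 1% mitochondrial UMIs 8 and with deep sequencing as a covariate 1. Without the 3 deeply sequenced libraries 9 ended besides the turned call. These were heat shock genes in both neuron classes, astrocytes and microglia, myelin genes in inhibitory neurons and astrocytes, microglial activation genes in astrocytes and oligodendrocytes, and astrocytic transport genes. With the median mitochondrial percent as a covariate 15 ended, among them all of these 9, clock genes in excitatory neurons and microglial activation genes in inhibitory neurons.

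By edgeR, before any setting was changed, single genes did not pass in this comparison. Of 68848 gene-class pairs 0 were called, with 1729 (2.51%) at an unadjusted p under 0.05, again fewer than this threshold gives with no difference. DESeq2 called 2, Lrfn5 in committed precursors and P22k15 in astrocytes. The synaptic adhesion gene Lrfn5 came closest, at 514 CPM in high, 455 CPM in low and 252 CPM in naive animals. Its log2 difference was 0.96 ± 0.20 (SE; edgeR adjusted p = 0.0829), and it was above the naive median in 12 of 12 cocaine libraries. The edgeR count became 2 without naive 2, and 1 without naive 3, low 3, naive 6 or low 6. Lrfn5 was the gene called without naive 6 (adjusted p = 0.0312) or low 6 (0.0243). It also passed in edgeR with no gene filter (0.00122), median UMIs (0.0113) or deep sequencing (0.000946) as a covariate, and without the 3 deeply sequenced libraries (0.0129). Without naive 2 the genes were Errfi1 in oligodendrocytes (0.0210) and Ddit4 in microglia (0.0161). In microglia, Ddit4, a stress-induced inhibitor of mTOR, stood at -0.85 ± 0.21 and Sqle at -0.68 ± 0.18. Oligodendrocytes gave Dusp1 at -0.77 ± 0.25, Aspa, which breaks down N-acetylaspartate, at -0.63 ± 0.17, Mt-nd6 at -0.51 ± 0.17 and the glycolytic gene Pfkl at -0.36 ± 0.12. Committed precursors gave the channel genes Cacna1e and Scn2a at 0.70 ± 0.23 and 0.51 ± 0.18, and oligodendrocyte precursors Vip at -0.69 ± 0.24, Dlgap2 at -0.63 ± 0.22 and Gria1 at -0.32 ± 0.11. Astrocytes gave Lpl at -0.72 ± 0.24, the chaperone gene Hspa5 at 0.42 ± 0.14 and Cck at -0.36 ± 0.12, and excitatory neurons Zbtb16 at -0.43 ± 0.12. Over all libraries the interneuron gene Sst stood at 195 CPM in oligodendrocyte precursors, 182 CPM in astrocytes and 126 CPM in committed precursors. Changes of Vip, Cck and other neuronal genes in these classes, Lrfn5 included, were not told apart from changes in free RNA. With doublets kept Lrfn5 fell to 0.33, Cacna1e to 0.25, Scn2a to 0.18, Gria1 to -0.15 and Dlgap2 to -0.42, and Mt-nd6 in oligodendrocytes stood at -0.0882 with at least 1000 genes per nucleus. The naming rule gave 40 gene-class pairs for this comparison, not all of which are given here. Of these, 1 shrank by more than 1.5 times when 1 library was left out, Dnaja1 in oligodendrocytes (0.35, and 0.22 without high 1), and 17 did in another setting. In simulated counts for this comparison, with 200 genes changed in each class, edgeR recovered 54.3% of genes changed 1.5-fold and 86.6% of those changed 2-fold. Recovery with fewer changed genes was not simulated.

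Class shares did not pass between cocaine and naive animals either. Microglia made up 4.37% ± 1.72 (SD, n = 12) of nuclei in cocaine and 5.75% ± 1.14 (SD, n = 7) in naive animals (two-sided exact permutation p = 0.0750, adjusted p = 0.525). Without high 6 the difference of -1.39 points became -1.07 (exact permutation p = 0.109). Inhibitory neurons made up 37.3% ± 8.49 and 33.2% ± 4.49 (exact permutation p = 0.278), a difference of 4.10 points that became 2.01 without high 6, and committed precursors 0.620% ± 0.200 and 0.745% ± 0.167 (exact permutation p = 0.184), a difference of -0.125 that became -0.0703 without naive 1.

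High animals alone were compared with naive animals on the same question. Each list change given for them was called by camera at its preset correlation only (smallest adjusted p = 0.276 with an estimated correlation). Mitochondrially encoded genes fell in high animals by a median of -0.66 in excitatory and -0.58 in inhibitory neurons (13 of 13 members in both), and cholesterol biosynthesis genes fell by -0.26 in astrocytes (19 of 19) and -0.11 in excitatory neurons (17 of 20). Myelin genes rose in microglia (0.49, 10 of 11) and immediate early genes rose in excitatory neurons (0.21, 20 of 21) and inhibitory neurons (0.16, 17 of 21). In committed precursors the sodium and calcium channel genes rose (0.39, 12 of 12), and myelin genes fell (-0.25, 13 of 14). Free RNA was not told apart from a change within the class for myelin genes in microglia or channel genes in committed precursors. Camera called 27 of 163 list-class pairs, 14 up and 13 down, with adjusted p = 2.07e-11 for cholesterol genes in astrocytes. The lowest value was adjusted p = 0.276 with an estimated correlation, again for cholesterol genes in astrocytes, so that 0 lists passed there (9 at an unadjusted p under 0.05), and 0 passed by fry (smallest adjusted p = 0.574). Adjusted over the list alone, 11 list members were called. By edgeR 0 genes were called, with 1704 pairs (2.48%) at an unadjusted p under 0.05. DESeq2 called 0, while Lrfn5 in committed precursors stood at 1.03 ± 0.22 (SE; edgeR adjusted p = 0.0926). The microglial share was 4.11% ± 1.73 (SD, n = 6) in high and 5.75% ± 1.14 (SD, n = 7) in naive animals (exact permutation p = 0.0495, adjusted p = 0.228). High 6 held 0.902% against 3.51% to 5.59% in the other high libraries, and without it the difference of -1.64 points became -0.999 (exact permutation p = 0.122). The number of called lists was 43 without high 6, and the number of called genes was 2 without high 1 and 1 without naive 2.

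Low animals were compared with naive animals in the same way. Their list changes, too, were called by camera at its preset correlation only (smallest adjusted p = 0.749 with an estimated correlation). Immediate early genes rose in low animals by a median of 0.36 in excitatory neurons (20 of 21 members), 0.39 in inhibitory neurons (20 of 21) and 0.34 in astrocytes (14 of 16). Glucocorticoid-responsive genes fell in oligodendrocytes (-0.57, 12 of 13), oligodendrocyte precursors (-0.31, 7 of 9), microglia (-0.26, 8 of 9) and astrocytes (-0.24, 11 of 14), and mitochondrially encoded genes fell in inhibitory (-0.46) and excitatory neurons (-0.41, 13 of 13 members in both). Camera called 30 of 163 pairs, 10 up and 20 down, with adjusted p = 7.50e-14 for immediate early genes in excitatory neurons. None passed with an estimated correlation (smallest adjusted p = 0.749 with an estimated correlation, 10 at an unadjusted p under 0.05) or by fry (smallest adjusted p = 0.990), and 8 list members were called when adjusted over the list alone. By edgeR 0 genes were called, with 1523 pairs (2.21%) at an unadjusted p under 0.05. DESeq2 called 3. They were Arhgef26 in excitatory neurons, at a log2 difference of -1.22, and in oligodendrocyte precursors Vegfa at 0.771 and Sparcl1 at -0.725. Microglia made up 4.62% ± 1.83 (SD, n = 6) of nuclei in low and 5.75% ± 1.14 (SD, n = 7) in naive animals (exact permutation p = 0.206, adjusted p = 0.939), and the difference of -1.13 points became -0.495 without low 6. The number of called lists was 15 without low 4 and 49 without low 6, and the number of called genes was 2 without naive 1, naive 2 or low 3 and 1 without high 1.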

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

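All tests of patterns are given with the other observations, and the values here come from a search of 261 groups of 6 or 7 libraries that was fixed in advance, run on genes that were in part chosen after the list results were seen. In 25 of the 261 groups, 1 library lay far from the others of its group by Dixon's criterion. Chance gives about 1 in 20, or 13.05 groups, and 9 of the 25 were in low 6, 4 in high 6 and 2 in naive 7, the libraries sequenced most deeply. High 1 and naive 4, which were not sequenced so deeply, also held 2 each.

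High 6, low 6 and naive 7 had 50343, 40217 and 36467 reads per nucleus, against 11967 to 17040, 12703 to 16198 and 12774 to 19201 in the rest of their groups. Low 6 also had a median of 4273 UMIs per nucleus (others 2206 to 2884) and 2453 genes (others 1436 to 1796). Excitatory neurons made up 28.2% of nuclei in low 6 (others 9.52% to 15.7%) and oligodendrocytes 4.32% (others 16.5% to 22.3%). Oligodendrocyte precursors made up 2.84% in low 6 (others 5.98% to 7.53%) and 1.19% in high 6 (others 5.23% to 6.78%).

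Among neuronal genes, Glo1 in excitatory neurons reached 80.9 CPM in low 6 (others 37.3 to 53.6), and Crh there reached 9.85 CPM in high 6 (others 2.06 to 4.92) and 9.40 CPM in low 5 (others 2.40 to 4.24). Mt-nd6 in excitatory neurons reached 49.9 CPM in high 1 (others 19.1 to 29.2), and in inhibitory neurons Hk2 reached 1.35 CPM in low 4 (others 0.293 to 0.551).

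In microglia, Pex5l reached 55.4 CPM in low 6 (others 18.6 to 31.4), Mog 59.7 CPM in low 2 (others 22.9 to 31.7) and Atp5mf 251 CPM in high 6 (others 132 to 167), while Sgk1 was at 42.7 CPM in naive 4 (others 81.6 to 104). In committed precursors Aldh5a1 reached 156 CPM in low 6 (others 60.7 to 94.9) and 144 CPM in naive 4 (others 55.8 to 78.3). In astrocytes Unc13b was at 4.80 CPM in high 1 (others 8.19 to 9.86) and 21.3 CPM in naive 3 (others 9.01 to 13.2), Oprm1 at 10.1 CPM in naive 2 (others 5.01 to 6.98) and Hspa5 at 292 CPM in naive 7 (others 200 to 236). Pfkl in oligodendrocytes was at 27.2 CPM in naive 5 (others 32.3 to 36.1).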

How the results depend on the processing

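Chosen after seeing the data were the settings without the 3 deeply sequenced libraries, with deep sequencing or the median mitochondrial percent as a covariate, and with at most 1% mitochondrial UMIs. No class share, subcluster share or inhibitory-excitatory difference passed in any setting run. With 1 library left out, 2 of 15 lists between high and low animals and 14 of 35 between cocaine and naive animals stayed called throughout, neither called gene did, and called lists of the comparisons of high or low with naive animals were followed as counts only. Pex5l was not tested with at least 1000 genes per nucleus. Few nuclei in microglia and committed precursors limit what could be seen there. Why a setting changed a result was not looked into, so for the changes given here the cause was not tested, while explanations of 3 patterns were tested as given with the other observations.

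Genes called between high and low animals (2 as reported) numbered 5 with no gene filter, 0 with the tag number series as a covariate, and 1 with DESeq2, only the groups compared, a minimum of 1000 genes per nucleus, doublets kept or at most 1% mitochondrial UMIs, and 0 to 3 with 1 library left out. Between cocaine and naive animals (0 as reported) they numbered 4 with no filter, 2 with DESeq2, the median UMI count or the median mitochondrial percent as a covariate, 1 without the deep libraries or with deep sequencing as a covariate, and 0 to 2 with 1 library left out. For high against naive animals they numbered 11 with no filter, 1 with 1000 genes, 2 with median UMIs, 3 with deep sequencing and 1 with mitochondrial percent, and 0 to 2 with 1 library left out. For low against naive animals they numbered 4 with no filter, 3 with DESeq2, 1 with doublets kept or median UMIs, and 0 to 2 with 1 library left out.

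Lists called between high and low animals (15) numbered 7 with no filter, 8 with 1000 genes, 32 with the tag number series and 9 to 30 with 1 library left out. For low against naive animals (30) they numbered 50 with the tag number series and 15 to 49 with 1 library left out, and for high against naive animals (27) 25 to 43. With an estimated correlation and with fry 0 were called in all 4 comparisons.

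Directions turned as follows. Without the deep libraries the dopamine and striatal list in inhibitory neurons of high against low animals had adjusted p = 0.588, Crh in excitatory neurons stood at -0.63, Glo1 in inhibitory neurons at -0.0383, and, for cocaine against naive animals, oxidative phosphorylation genes in excitatory neurons were called in the opposite direction (adjusted p = 0.0295) and myelin genes in inhibitory neurons had 0.894. With mitochondrial percent, a covariate computed from the UMIs of mitochondrially encoded genes, these 2 lists had 0.453 and 0.311, Crh in excitatory neurons stood at -0.0739, and Glo1 at -0.0037 in excitatory and -0.0065 in inhibitory neurons. With the tag number series oxidative phosphorylation genes had 0.909, and Crh and Gabrb2 in inhibitory neurons stood at 0.0025 and -0.0155. Crh in excitatory neurons stood at -0.0289 with DESeq2 and -0.0296 with deep sequencing, Glo1 there at -0.0016 with no filter, and Mt-co1 in committed precursors at 0.12 with at most 1% mitochondrial UMIs.

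With 1 library left out, the log2 difference of Crh ran from -0.49 to 0.37 in excitatory and -0.18 to 0.16 in inhibitory neurons, that of Glo1 from -0.19 to 0.21 and -0.17 to 0.16, and that of Gabrb2 in inhibitory neurons from -0.0144 to 0.0932. Adjusted p ran from 3.11e-05 to 0.926 for the dopamine and striatal list, which turned without low 6. Without high 6 the direction turned for oxidative phosphorylation genes in astrocytes (range 3.76e-09 to 0.735), oligodendrocyte precursors (1.37e-07 to 0.976) and committed precursors (3.95e-08 to 0.811) and ribosomal genes in astrocytes (2.98e-08 to 0.733). For cocaine against naive animals, oxidative phosphorylation genes in excitatory neurons ran from 1.68e-05 to 0.698 and turned without high 6 (0.550) or low 6 (0.698).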

Other observations

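Tests chosen after the result was seen were those of free myelin RNA, of cytoplasm, of handling, of the deeply sequenced libraries for mitochondrially encoded genes, of splits that kept the deeply sequenced libraries balanced, and the splits of gene calls, list calls and the inhibitory-excitatory difference between high and low animals. The criteria for free myelin RNA and for cytoplasm were also changed after their values were known, as stated with each. The splits between high and low animals were first run with fewer draws and then raised to 100, as for the other comparisons. A test of inhibitory subcluster shares between cocaine and naive animals was also tried, passed for none and was left out.

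Activity genes were counted per nucleus as a share of nuclei with at least 1 UMI of Fos, Fosb, Npas4, Arc or Egr1 after thinning to 1500 UMIs. In excitatory neurons the share was 21.2% ± 5.17 (SD, n = 12) in cocaine and 17.1% ± 2.73 (SD, n = 7) in naive animals (two-sided exact permutation p = 0.0754, adjusted p = 0.146 over 5 classes). In inhibitory neurons it was 15% ± 2.65 (SD, n = 12) and 12.9% ± 1.97 (SD, n = 7) (exact permutation p = 0.0874, adjusted p = 0.146). Oligodendrocytes, which gave a background from free RNA at the same depth, held 7.28% ± 2.46 and 7.01% ± 1.07 (exact permutation p = 0.788). In microglia it was 8.23% ± 5.85 and 15.9% ± 7.79 (exact permutation p = 0.0267, adjusted p = 0.134), from 256 and 309 nuclei, since 3997 and 2738 nuclei had too few UMIs. Without thinning, over all nuclei, the microglial shares were 7.52% and 7.47% (exact permutation p = 0.969). Unthinned shares were 45.8% and 42.0% in excitatory (exact permutation p = 0.338) and 27.2% and 25.5% in inhibitory neurons (0.413), where depth also counts. Without the 3 deeply sequenced libraries, the thinned shares gave permutation p = 0.174 in excitatory neurons, 0.147 in inhibitory neurons and 0.0109 in microglia, not adjusted.

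Myelin genes were higher in microglia of high than of low animals, with a median log2 difference of 0.58. Oligodendrocyte RNA in microglial droplets may contribute, since other oligodendrocyte transcripts had a median of 0.36 there (quartiles 0.14 to 0.59), past the level set by the criterion. They were not tested as a list, and 4 of the 16 had an unadjusted p under 0.05. Among the 16, Rasgrp3 and Enpp6 stood higher in microglia than in oligodendrocytes, so neither traces oligodendrocyte RNA there. Free myelin RNA in every droplet stayed open: the summed myelin CPM rose in astrocytes by 46.1 (SE 103), 8.58% of the rise of 537 (SE 249) in microglia, a spread too wide to decide. A first criterion, a list median above 0 in 4 of 4 other classes, had been met at 0.08 to 0.11 and would have counted for it. Of 100 splits of the libraries 5 gave a median as large as 0.58 (highest other 0.74), so chance could not be excluded (4 of the 55 with 1 deeply sequenced library in each group, as in the real one). Uptake of myelin by microglia, which was not tested, stays open. With doublets kept Mbp, Mobp and Mog differed by 0.33, 0.44 and 0.28.

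Mitochondrially encoded genes were lower in cocaine than in naive animals, by a mean of -0.37 over the classes. The 3 deeply sequenced libraries were not its whole cause, since 82.0% of its size stayed without them. More cytoplasm carried along with the nuclei of naive libraries could not be decided: ribosomal protein genes had a median below 0 in 3 of 7 classes, which alone would have counted against it, but a condition on the spread, added afterwards, was not met, since the summed ribosomal CPM differed by -0.0031 ± 0.133 (SE) on the log2 scale against -0.47 ± 0.218 for the mitochondrial genes. Of 100 splits 8 gave a mean as large as 0.37 (highest other 0.503), so chance could not be excluded. Of the 44 splits among them with 1 deeply sequenced library in the smaller group, as in the real one, 2 did, the real one included (highest other 0.421). That is 4.55%, on a subset chosen after the result and resting on 1 other split, so it was left open whether chance is enough. A lasting effect of cocaine, or of the self-administration procedure, on mitochondrial transcripts stays open. So does the loss of mitochondrial RNA during isolation, and neither was tested.

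Immediate early genes were higher in neurons of cocaine than of naive animals, with a mean of 0.271 over both neuron classes. The 3 deeply sequenced libraries were not its whole cause, since 85.3% of its size stayed without them. A response of all cells to handling or tissue processing could not be told apart from it, since the median was above 0 in 3 of 4 glial classes (0.23 in astrocytes, 0.09 in oligodendrocyte precursors, 0.07 in oligodendrocytes and -0.01 in microglia), where the criterion had named 5 classes. A larger share of neurons with such UMIs may also contribute, with a smaller permutation p of 0.0754. The inhibitory cluster led by Fosb and Fos was larger in cocaine animals, which goes with it (1.28% against 0.790% of nuclei, exact permutation p = 0.00460, adjusted p = 0.129 over 28 clusters). Since these genes mark the cluster, nuclei with more of their UMIs enter it whatever the cause, so the explanation stays open. Of 100 splits 12 gave a mean as large (highest other 0.399), as did 7 of the 44 balanced ones, so chance could not be excluded. An effect of cocaine history, or of the procedure that went with it, stays open.

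Over 100 splits of the same libraries into groups of the same sizes, chance could not be excluded for edgeR calls of genes or for camera calls of lists at the preset correlation, where these were above 0. Calls of DESeq2 and of members over the list alone were not split. Between high and low animals 19 splits gave at least the 2 genes called (highest other 2947) and 92 at least the 15 lists (highest other 84). Between cocaine and naive animals 65 gave at least 35 lists (highest other 103), for high against naive animals 72 at least 27 lists (highest other 93), and for low against naive animals 64 at least 30 lists (highest other 77). Counts of 0 were not tested by this, since all 100 splits give at least 0 calls whatever the data. That holds for genes between cocaine and naive animals (highest other 6063), high and naive animals (highest other 33) and low and naive animals (highest other 38), and for the inhibitory-excitatory difference in limma (highest other 2).

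Splits that called so many genes point to a structure of the samples: the split with 6063 put all 3 deeply sequenced libraries in 1 group, and those with 2947 and 2669 put high 6 and low 6 in the same group, while splits that parted them called at most 4. Each real group held 1 such library, so the splits with that balance, the real one included, were also counted alone. Between high and low animals 8 of 55 gave at least 2 genes and 47 at least 15 lists (median of the others 24.5, highest 75). At least as many lists as in the real split came from 16 of 44 between cocaine and naive animals (median of the others 27, highest 67), 33 of 59 for high against naive animals (27, highest 52) and 27 of 61 for low against naive animals (27.5, highest 44). Chance could not be excluded there either.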
